A study of Gallus gallus with 4 samples.

How the data were processed

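Dorsal root ganglia with their attached nerves from chicks (Gallus gallus) were profiled by single-nucleus RNA sequencing in 4 libraries, 2 labelled control and 2 labelled TRPA1 inhibitor. Per the labels, the eggs had been incubated under intermittent high temperature, with or without injection of an inhibitor of TRPA1, an ion channel of sensory neurons that opens to irritants and, in birds, to heat. Nothing in the labels says which animals or how many went into a library, so the p-values measure only the spread between these libraries, which may be partly technical.

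Per the labels' protocols, frozen tissue was homogenised and passed through strainers, single nuclei were captured in droplets with barcoded beads, and each molecule received a unique molecular identifier (UMI). Per the file headers, PISA v0.12b wrote the matrices, and the deposited values are whole-number counts of UMIs per gene and nucleus with no normalization. The aligner, genome build, annotation, strand setting and method of calling nuclei are not given in the sources used here. Because strand is not stated, reads of overlapping genes cannot be told apart, and genes with a near-identical copy may share reads. The files named 22766 genes over the 4 libraries, of which 22740 matched a symbol in a reference table of assembly GRCg7b. That table was used only for names, neighbouring genes and gene spans, and 8311 names were numbered placeholders.

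The files held 4253 and 4660 barcodes in the control libraries and 3418 and 3005 in the inhibitor libraries. Total UMIs were 9971541 and 10444477 against 6751732 and 6726681. A single gene name, FRMD8, took 61.4% of all UMIs and had a UMI in every barcode, while the second most abundant took 0.421%. Whether these UMIs come from the FRMD8 gene or from another RNA counted under its name is not known. Changes of FRMD8 below are subject to that doubt. CPM values below are computed over all UMIs, FRMD8 included. Because UMIs mark molecules, repeated reads of a molecule count once, and intervals given for single libraries are exact binomial or Poisson 95% intervals of counting error only.

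Nuclei with at least 200 genes and at most 5% mitochondrial UMIs were kept, which removed 105 and 185 control barcodes and 339 and 98 inhibitor barcodes with too few genes and 81 and 81 against 62 and 56 with too many mitochondrial UMIs. Scrublet called 4 doublets, 0.0279% of the nuclei, so the caller did not work and doublets largely remain. Removing the top 5% of doublet scores in each library served as an alternative. The 14329 nuclei left had a median of 1294, 1294, 1186 and 1225 UMIs in control 1, control 2, inhibitor 1 and inhibitor 2, or 502, 486, 420 and 464 without FRMD8. They were clustered in Python 3.11.15 with scanpy 1.11.5 (normalization and variable genes), scikit-learn 1.9.0 (neighbours) and the Leiden method of igraph. The settings were 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1, without integrating the libraries. Clusters were named from marker lists and called "like" a cell type. Neurons were clustered again at resolution 0.5.

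The tests, gene lists, markers, rule for named genes and first set of alternatives were chosen before the data were examined. The weighting of the neighbour graph was chosen after a first clustering had been seen, to make it repeatable. The assignment of clusters to names, the removal of a central neuron-like subcluster from the sensory neurons, and leaving clusters 5, 8, 10, 15 and 16 without a name also followed a look at the clusters. The central neuron-like nuclei made up 0.901% of control and 0.695% of inhibitor nuclei, cluster 15 made up 0.549% and 0.755%, and cluster 16 made up 0.649% and 0.496%.

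For each class with at least 20 nuclei in every library, UMIs were summed per library and tested with edgeR 4.0.16 (quasi-likelihood test, filterByExpr defaults, TMM factors, R 4.3.3) for inhibitor against control, with Benjamini-Hochberg adjustment over the genes of the class and a threshold of 0.05. An adjusted p below is from this test unless another is named. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were alternatives. Class shares were tested with edgeR on numbers of nuclei. An exact two-sided permutation test of 2 against 2 libraries cannot give a p under 0.333, so none is reported. Gene lists were tested with limma's camera on voom values at a preset correlation of 0.01, adjusted over the lists of a class, and again with an estimated correlation and with fry. Differences of effect between classes were tested with limma on the within-library difference of log2 CPM (prior count 2).

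The lists covered somatosensory channels, other voltage-gated channels, neuropeptides and neurotrophin receptors, synaptic release, calcium signalling, immediate-early genes, nerve injury, heat shock, endoplasmic reticulum stress, oxidative stress, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, glycolysis and hypoxia, cholesterol synthesis, myelin, repair Schwann cells, inflammation, interferon response, extracellular matrix, axon guidance, glucocorticoid and thyroid response, the circadian clock, the cell cycle, apoptosis, red cell genes and chromosome W genes. A list was tested where at least 3 of its genes were. The chromosome W list had 2 tested genes in sensory neurons, 1 of them lower in the inhibitor libraries, and so no list test.

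Genes were named by rule. In sensory neurons, Schwann cells and satellite glia these were up to 10 genes per direction with the largest change among those past the test, with both inhibitor libraries on the same side of both controls, a mean of at least 20 CPM and a proper symbol. In other classes up to 3 per direction were named, and where fewer than 5 passed, the 5 with the lowest p were given as not past the test. Genes past the test in the most classes (up to 10 per direction), members of the lists, TRPA1 and TRPV1 could also be named. Some items that the rule names are not reported here, but the counts include them. Shares of nuclei with a UMI were compared also after thinning each nucleus to 800 UMIs.

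On simulated data drawn from the real means and library sizes, the edgeR step in sensory neurons (11604 genes) recovered 21.0%, 77.8% and 95.2% of genes changed by 0.5, 1 and 2 on the log2 scale. In Schwann cells (5461 genes) it recovered 4.55%, 41.0% and 80.4%, in satellite glia (6094 genes) 4.69%, 41.7% and 84.7%, and in fibroblasts (7171 genes) 8.06%, 55.7% and 86.0%. The test of the difference between neurons and satellite glia (6396 genes) recovered 25.5% and 91.0% of differences of 1 and 2. Replicate libraries differed in class makeup (chi-square 29.7, p = 0.00844 for control; 48.8, p = 9.64e-06 for inhibitor; chi-square tests over nuclei). The mean chi-square of neuron UMIs between replicates was 1.70 in control and 1.64 in inhibitor, which 5 and 14 of 100 random splits of the pooled nuclei reached, against 4.58 between control 1 and inhibitor 1. In the inhibitor libraries 41 of 100 splits reached the value of Schwann cells and 43 that of satellite glia, and in control 10 and 7. These glial values and that of inhibitor neurons do not show that replicates differ by more than sampling. In fibroblasts 0 of 100 splits reached the value in control and 5 that in inhibitor. Replicates were kept as separate libraries, as deposited.

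Alternatives were other scaling factors, no or stricter gene filters, DESeq2, limma-voom, a replicate block, another resolution and centring per library before clustering. Others were at least 300 genes per nucleus, equal library totals, leaving out each library and, for the TRPA1 level, nuclei thinned to 800 UMIs. Those added after the data were seen were leaving out FRMD8, the top doublet scores, cluster 7 of the neurons, cluster 11 of the fibroblasts, chromosomes W and Z or the meningeal and spinal cord classes, keeping the central neuron-like nuclei, and giving neuron subclusters equal shares of UMIs.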

Results

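The data were UMI counts from nuclei of dorsal root ganglia and attached nerves of 1-day-old chicks, in 2 control and 2 TRPA1 inhibitor libraries of 6726681 to 10444477 UMIs. They address what blocking TRPA1 during incubation under intermittent heat left behind in the cells of the ganglion. Values with ± are the mean and SD over 2 libraries, fold changes are inhibitor over control on the log2 scale, and SE is the standard error of the fit.

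Sensory neurons, glia, fibroblast-like and meningeal-like nuclei made up most of the 14329 nuclei. Sensory neuron-like nuclei numbered 721 and 844 in the control and 734 and 561 in the inhibitor libraries. Schwann cell-like nuclei numbered 348, 418, 408 and 368 in the same order, satellite glia-like nuclei 634, 712, 553 and 591, and fibroblast-like nuclei 935, 1078, 654 and 622. Sympathetic neuron-like, endothelial-like and cycling nuclei were fewer.

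Myelinating Schwann cell-like nuclei held a larger share in the inhibitor libraries, 11.3% ± 0.233 against 7.12% ± 0.715 (adjusted p = 0.00111, edgeR on nuclei). Meningeal-like nuclei held a smaller one, 5.81% ± 0.713 against 9.76% ± 1.57 (adjusted p = 0.00065). Cluster 10, left without a name, fell from 3.39% ± 0.352 to 0.989% ± 0.0393 (adjusted p = 5.54e-07), and cluster 5, led by CCN2 and matrix genes, from 7.96% ± 0.367 to 5.45% ± 1.47 (adjusted p = 0.0105). Sensory neurons (18.5% ± 1.05 and 22.0% ± 3.29), satellite glia (15.9% ± 0.437 and 19.5% ± 1.69) and fibroblasts (23.8% ± 1.10 and 21.8% ± 0.0937) did not pass, with adjusted p of 0.171, 0.131 and 0.437. Dissection can set these shares, and in each of the 4 clusters past the test a leading gene itself differed between the groups (among them MLIP in myelinating Schwann cells, TRPM3 in meningeal nuclei and COL8A1 in cluster 5). Without control 1 only 1 class passed.

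**Figure D1:**
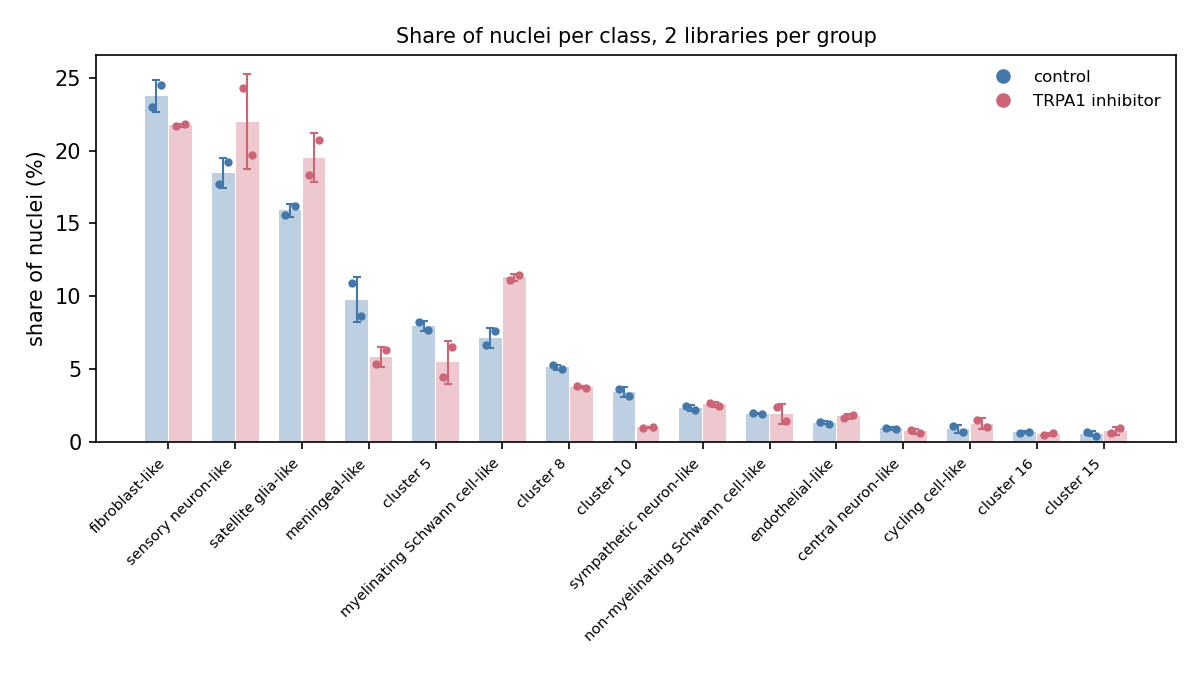
Share of nuclei (y axis, %) in each class (x axis) for control and TRPA1 inhibitor libraries, with bars for means, points for the 2 libraries of a group and error bars for SD. Cluster 10 lies at 3.39% in control and 0.989% in inhibitor libraries.

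TRPA1, the target of the inhibitor, was lower in sensory neurons of the inhibitor libraries. Its level fell from 93.7 ± 4.95 to 57.4 ± 5.11 CPM, a log2 fold change of -0.66 (SE 0.12, adjusted p = 0.000182), on 346 and 395 UMIs in the control and 168 and 149 in the inhibitor libraries. A TRPA1 UMI was present in 16.4% ± 0.618 of control and 11.2% ± 1.57 of inhibitor neurons. After thinning to 800 UMIs, which left out 43 and 1 neurons of the inhibitor libraries and 0 of the control libraries, the shares were 5.47% ± 0.477 and 3.11% ± 0.105. Outside the neurons, before thinning, the share was higher in inhibitor libraries in Schwann cells, at 0.670% ± 0.271 in control and 1.54% ± 0.252 in inhibitor libraries. It was lower in satellite glia (1.86% ± 0.0473 and 0.881% ± 0.289) and fibroblasts (1.41% ± 0.282 and 0.788% ± 0.250). The Schwann cell shares stand for few nuclei among 348 and 418 in control and 408 and 368 in inhibitor libraries. At 3.58 ± 1.37 and 8.34 ± 1.53 CPM, TRPA1 was not among the genes tested in Schwann cells, so no direction is claimed there. Median UMIs per nucleus were 4207, 3439, 2507 and 3706 in neurons of control 1, control 2, inhibitor 1 and inhibitor 2, and 1076, 1073, 912 and 974 in satellite glia. TRPV1, the capsaicin receptor, fell as well, from 181 ± 1.11 to 119 ± 2.04 CPM (log2 fold change -0.55, adjusted p = 8.86e-05; -0.36 with equal subcluster shares, adjusted p = 0.0234). Each neuron cluster held nuclei of both groups, in different proportions. Cluster 7 held 14.8% and 21.4% of control but 35.1% and 35.5% of inhibitor neurons. Its leading genes included TRPM8, TRPA1, NPW, mt-ND6 and mt-COX2. The call on the TRPA1 level was lost without cluster 7 (-0.56, adjusted p = 0.0518) and with thinned nuclei (-0.43, adjusted p = 0.394), while over the fits that left out 1 library the value ran from -0.79 to -0.56.

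Across the somatosensory channel list, 9 of 25 tested genes fell and 1 rose in sensory neurons. The largest fall was in TRPV3, a warmth-gated channel, from 665 to 360 CPM (log2 fold change -0.84, adjusted p = 6.77e-10). The cold and menthol receptor TRPM8 fell from 74.7 to 48.3 CPM (-0.58), and the sodium channels of pain fibres SCN9A and SCN11A by -0.40 and -0.41. PIEZO2, the touch channel, rose from 318 to 422 CPM (0.45, adjusted p = 0.0003). Adjusted over the list alone, 11 fell and 3 rose. The list's median was -0.25 (camera adjusted p = 0.00012; adjusted p = 0.41 with an estimated correlation). Beside it, 20 genes that sensory neurons held at over 5 times the level of every other class had a median of -0.39 (95% bootstrap interval -0.56 to -0.33); 3 of them (TRPV1, TRPV3 and SCN11A) are also in the channel list, and the other 17 had a median of -0.37 (interval -0.57 to -0.27). Without cluster 7, 3 of 24 fell and 0 rose, and TRPM8 (-0.34, adjusted p = 0.4) and PIEZO2 (0.23, adjusted p = 0.172) did not pass. With equal shares of UMIs per neuron subcluster 5 of 24 fell and 0 rose by edgeR's test, and SCN11A (-0.20, adjusted p = 0.062), TRPM3 (-0.34, adjusted p = 0.0621), TRPC1 (-0.40, adjusted p = 0.104), ASIC2 (-0.31, adjusted p = 0.169) and PIEZO2 (0.20, adjusted p = 0.172) did not pass.

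**Figure D2:**
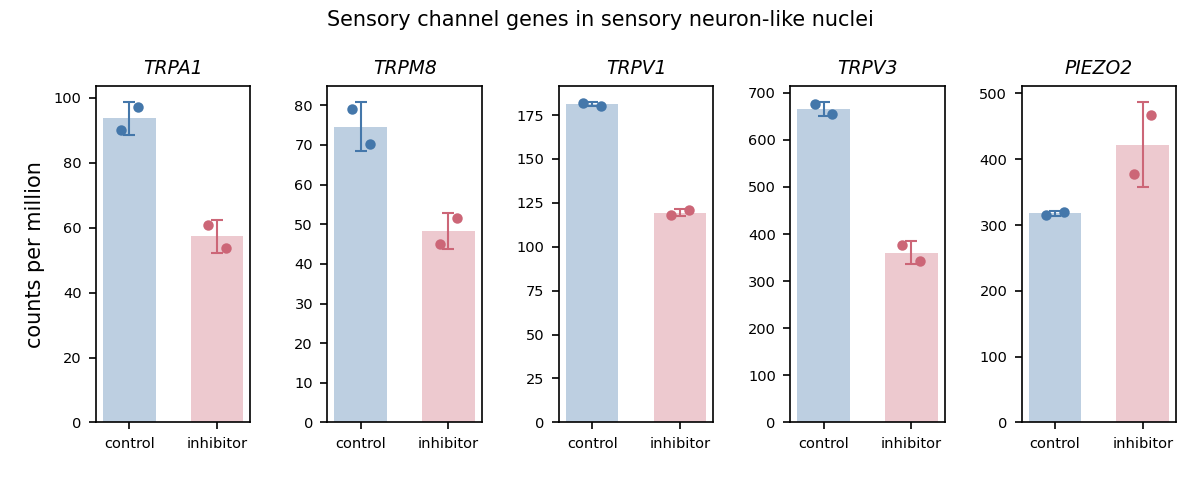
CPM (y axis) of 5 sensory channel genes in sensory neuron-like nuclei of control and inhibitor libraries (x axis), with bars for means, points for the 2 libraries and error bars for SD. TRPA1, TRPM8, TRPV1 and TRPV3 are lower and PIEZO2 is higher in the inhibitor libraries.

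Of 11826 genes tested in sensory neurons, 1652 passed, 920 higher and 732 lower in the inhibitor libraries. The largest rises included FOS, an activity-induced transcription factor, from 29.1 ± 10.1 to 79.6 ± 10.9 CPM (log2 fold change 1.51, SE 0.15, adjusted p = 1.27e-09), and NR4A3, a nuclear receptor of the same response (1.37). RAG2, known for immune receptor recombination, rose by 1.72, the peptide NPW by 1.46, the calcium buffer CALB2 by 1.31, and the ribosomal genes RPS29, RPL36 and RPL23A by 1.53, 1.42 and 1.25. SVBP, a partner of tubulin-trimming vasohibins, rose by 1.51 and METTL22, a methyltransferase, by 1.38. In GRCg7b RAG2, METTL22 and, named below, EYS span 565728, 660197 and 676382 bp. Where within these spans their UMIs lay was not examined. Falls included the kinase NEK3 (-1.37, SE 0.20, adjusted p = 3.47e-06), PAF1 of the elongation machinery (-1.23) and GRIN3B, an NMDA receptor subunit (-1.14). TECPR1 (-1.04), UXS1 (-1.02), AHSA2 (-0.99), MMEL1 (-0.93), CAB39L (-0.93) and JAM3 (-0.92) fell as well. All 20 genes chosen by the rule stayed past the test whichever library was left out. Without cluster 7, which NPW marks, NPW (0.46, adjusted p = 0.44) and CALB2 (0.35, adjusted p = 0.532) did not pass.

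The number of neuron genes depended on the tool, the nuclei and the libraries included. It was 297 with DESeq2, 616 without cluster 7, 810 without control 1, 889 without control 2 and 962 without inhibitor 2. Scaling by library size alone gave 811 higher and 906 lower.

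Several lists rose in sensory neurons. All 13 mitochondrially encoded transcripts rose (median 0.78, camera adjusted p = 8.12e-24), and of 70 ribosomal protein genes 52 rose and RPL27 fell (median 0.65, adjusted p = 4.22e-39; adjusted over the list alone, 60 and 2). Among 17 immediate-early genes 6 rose, ATF3 (1.11), EGR1 (1.42), FOS, JUND (0.60), MAFF (0.89) and NR4A3, with 6 also adjusted over the list alone (median 0.31, adjusted p = 0.00137). JUND and MAFF were lost without cluster 7 (adjusted p = 0.18 and 0.0598). Among 24 cholesterol synthesis genes 7 rose, among them HMGCS1 (0.69) and the regulator SREBF2 (0.43), and 9 adjusted over the list alone (median 0.40, adjusted p = 0.00012). Of 16 genes listed for repair Schwann cells, EGR1, GAP43 (0.36), NGFR (0.38), RUNX2 and SHH (1.02) rose, with 6 adjusted over the list alone. GAP43 is a growth cone protein and NGFR a neurotrophin receptor that neurons also use (median 0.35, adjusted p = 0.00177). Of 44 nuclear oxidative phosphorylation genes 8 rose and UQCRC1 and UQCRC2 fell, 9 and 2 adjusted over the list alone (median 0.23, adjusted p = 0.00822). With an estimated correlation none of these 6 passed: adjusted p = 0.41 with an estimated correlation for 5 of them and adjusted p = 0.881 with an estimated correlation for oxidative phosphorylation, whose call was also lost without control 2 or inhibitor 1 (adjusted p up to 0.295). With equal shares of UMIs per neuron subcluster the mitochondrial list had 4 higher and mt-ND6 lower (-0.37) of 12, with mt-COX3, mt-ND4 and mt-ND5 also under 0 (median 0.21, adjusted p = 0.0248; adjusted p = 0.541 with an estimated correlation). Mitochondrial transcripts mark nuclei that the inhibitor libraries hold more of: mt-ND6 and mt-COX2 are among the leading genes of cluster 7, and 9 such transcripts lead subcluster 5, with 44 and 63 control and 103 and 70 inhibitor neurons. Without cluster 7 it had 6 higher of 13 (median 0.44). Oxidative phosphorylation had 1 higher and 1 lower of 44 with equal shares (median 0.10, adjusted p = 0.707) and 0 and 1 without cluster 7 (adjusted p = 0.672). The repair list had 3 higher of 14 with equal shares, where NGFR (0.093) and SHH (0.63) did not pass, and the ribosomal list kept a median of 0.59.

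The remaining 19 lists did not pass in sensory neurons. Heat shock genes, relevant to heated eggs, had 2 higher and 1 lower of 37 tested, or 1 and 1 adjusted over the list alone (median 0.01, camera adjusted p = 0.876). Among neuropeptides and neurotrophin receptors, NTRK2 (0.75) and NTRK3 (0.55), receptors of touch and position neurons, rose and the pain peptide CALCA (-0.53) fell, with a list median of 0.04 (adjusted p = 0.876). With equal shares of UMIs per neuron subcluster none of these 3 passed: NTRK2 lay at 0.39 (edgeR adjusted p = 0.121), NTRK3 at 0.47 (0.0869) and CALCA at -0.23 (0.356). Axon guidance had 12 higher and 7 lower of 56 (14 and 7 adjusted over the list alone; median 0.08, adjusted p = 0.25), calcium signalling 7 and 7 of 38 (11 and 8; median 0.02, adjusted p = 0.876), potassium, calcium and HCN channels 4 and 8 of 40 (7 and 8; median 0.05, adjusted p = 0.796), nerve injury 4 and 0 of 21 (4 and 0; median 0.13, adjusted p = 0.25) and synaptic release 3 and 2 of 30 (3 and 2; median 0.12, adjusted p = 0.595). With equal subcluster shares these counts were 6 and 1 of 56, 1 and 1 of 37, 2 and 4 of 40, 2 and 0 of 20, and 0 and 0 of 30. Axon guidance passed without cluster 7 (adjusted p = 0.0481), though not with an estimated correlation (adjusted p = 0.806). Medians were 0.04 for oxidative stress (adjusted p = 0.678), 0.12 for glycolysis (0.777), 0.44 for inflammation (0.777), -0.06 for matrix (0.709), -0.12 for the clock (0.595) and -0.07 for the cell cycle (0.796). They were 0.02 for myelin, -0.08 for interferon, -0.08 for glucocorticoid and thyroid response and -0.02 for apoptosis, each with adjusted p of 0.876, and -0.28 for red cell genes and -0.00 for endoplasmic reticulum stress, each with adjusted p of 0.595.

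**Figure D3:**
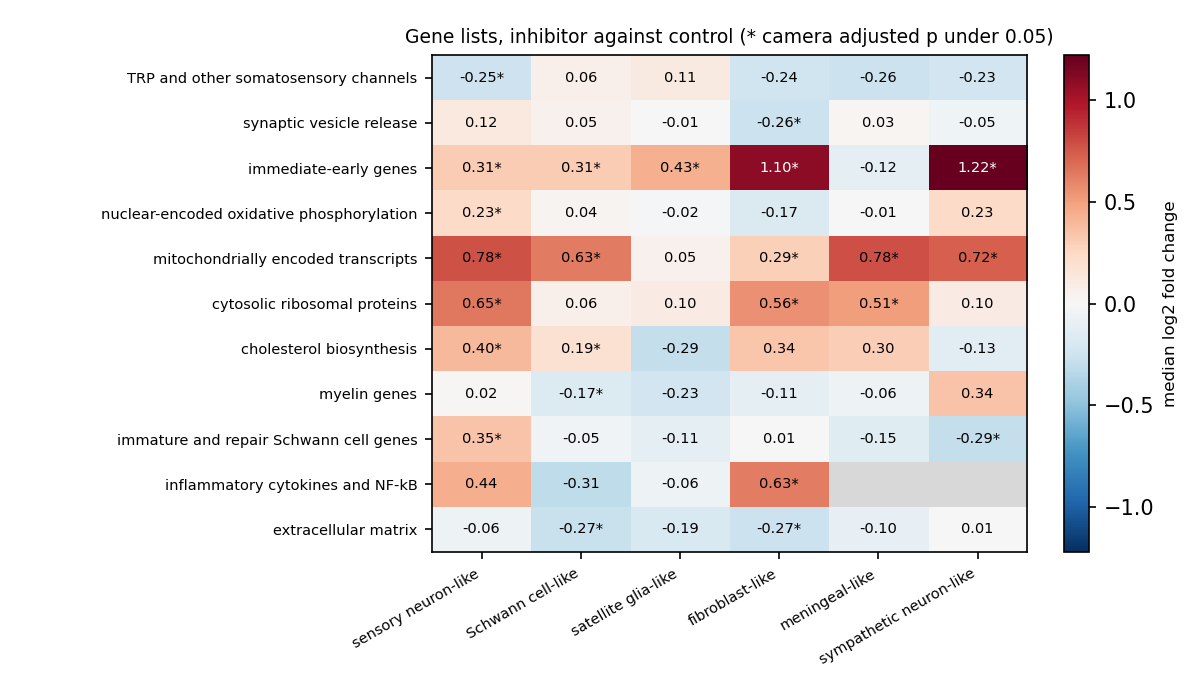
Median log2 fold change, inhibitor over control, of each gene list (rows) with a call in at least 1 of the 6 classes shown (columns), with an asterisk for a camera adjusted p under 0.05 at the preset correlation and grey where the list was not tested. The ribosomal list has 0.65 in sensory neurons and 0.56 in fibroblasts.

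In Schwann cells, FOS rose from 34.9 ± 2.29 to 113 ± 31.7 CPM and the photoreceptor-linked gene EYS from 9.66 ± 2.95 to 47.7 ± 8.48 CPM, while TULP1 fell from 515 ± 55.0 to 258 ± 10.9 CPM. Of 5820 genes tested, 43 passed, 30 higher and 13 lower. The log2 fold changes were 1.83 for FOS (adjusted p = 4.37e-07), 2.41 for EYS (adjusted p = 4.83e-05) and -0.84 for TULP1 (adjusted p = 1.24e-05). RAG2 (1.73), the transcription cofactor LMCD1 (1.72), the cadherin CDH9 (1.38), METTL22 (1.34), mt-ATP6 (1.15), mt-ND3 (1.09), mt-CYTB (0.99) and PHLDA2 (0.97) also rose. The glutamate receptor GRIA1 (-1.18), HEBP2 (-1.08), RTKN2 (-0.84), the lipoprotein APOA1 (-0.81), the cartilage collagen COL2A1 (-0.77), FKBP5 (-0.70), MLIP (-0.62) and PTPDC1 (-0.57) fell. Of the 20 genes chosen by the rule 5 stayed past the test whichever library was left out, and the total was 18 without control 1, 28 without control 2, 24 without inhibitor 1 and 14 without inhibitor 2. DESeq2 called 10, and scaling by library size alone, which set the median of all genes at -0.16, gave 14 higher and 37 lower.

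Mitochondrially encoded transcripts were higher in Schwann cells, 6 of 12 (8 adjusted over the list alone; median 0.63, camera adjusted p = 4.98e-18; adjusted p = 0.26 with an estimated correlation). The cholesterol list had SREBF2 higher (0.74) among 22 genes, 4 adjusted over the list alone (median 0.19, adjusted p = 0.0034), and the immediate-early list had FOS among 7, 2 adjusted over the list alone (median 0.31, adjusted p = 0.0109). The myelin list had 1 lower among 16 genes (median -0.17, adjusted p = 0.00648), with 1 higher and 1 lower adjusted over the list alone, and the matrix list had 0 of 33 past edgeR's test either way (median -0.27, adjusted p = 0.00721). With an estimated correlation the adjusted p was 0.834 for myelin and 0.955 for the other 3. All 5 calls were lost without control 1 and without control 2 (adjusted p up to 0.999).

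In satellite glia, FOS rose from 23.4 ± 1.86 to 72.6 ± 7.8 CPM and IL13RA2, a decoy receptor for interleukin 13, from 4.75 ± 0.635 to 44.2 ± 22.9 CPM, while TULP1, a tubby-family gene known from photoreceptors, fell from 431 ± 11.9 to 193 ± 31.2 CPM. Of 6482 genes 56 passed, 40 higher and 16 lower. The log2 fold changes were 1.67 for FOS (adjusted p = 0.00156), 3.22 for IL13RA2 (adjusted p = 0.00064) and -1.10 for TULP1 (adjusted p = 1.7e-06). TTN, the muscle protein titin (2.04), EGR1 (1.75), the serine synthesis enzyme PHGDH (1.74), EPHA4 (1.68), BMPR1B (1.65), CACNA2D3 (1.58), CTNNA3 (1.57) and PLSCR1 (1.55) also rose. FOS and EGR1 are also leading genes of cluster 11, a fibroblast-like cluster described below. NPY (-1.13), FKBP5 (-0.93), USP43 (-0.88), COL2A1 (-0.87), CSRP2 (-0.84), ANKRD44 (-0.78), WSB1 (-0.68) and GAS2L3 (-0.60) fell. The immediate-early list passed on 8 genes, with EGR1 and FOS higher and 3 adjusted over the list alone (median 0.43, camera adjusted p = 0.00694; adjusted p = 0.936 with an estimated correlation). That call was lost without control 2, inhibitor 1 or inhibitor 2, 5 of the 20 genes chosen by the rule stayed past the test whichever library was left out, and the total was 31 without control 2, 37 without inhibitor 1 and 33 without inhibitor 2. DESeq2 called 11, limma-voom 28, no gene filter 93, Leiden resolution 0.5 gave 20 and clustering centred per library 124, and scaling by library size alone gave 49 higher and 34 lower.

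Effects differed between classes for few genes by the test of the difference: 4 of 5751 between sensory neurons and Schwann cells and 15 of 6396 between sensory neurons and satellite glia. NEFM, a neurofilament, rose in neurons (0.60, adjusted p = 1.3e-05) and lay at -0.10 in Schwann cells and -0.04 in satellite glia. It is among the markers of cluster 7, whose share was larger among inhibitor neurons. Between Schwann cells and satellite glia limma called 0 of 5305 genes, with 347 at an unadjusted p under 0.05 and 0 with a prior count of 0.5. The first count was 15 without control 1, 0 without inhibitor 1 and 1 without inhibitor 2, the second 35 without inhibitor 1 and 98 without inhibitor 2, and the third 1, 1 and 5 without control 1, inhibitor 1 and inhibitor 2.

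Fibroblast-like nuclei showed the largest rises. CCL4, a chemokine, had 0 UMIs in the control libraries and 71.4 ± 14.9 CPM in the inhibitor libraries, 62.0-fold above a floor of 3 counts over the control group, with a lower counting limit of 49.5-fold. The acute-phase gene SAA rose from 2.24 ± 0.806 to 97.5 ± 71.0 CPM, EXFABP, a lipocalin, from 4.98 ± 0.0695 to 126 ± 13.7, and FOS from 45.5 ± 0.72 to 448 ± 9.19 (log2 fold change 3.28, adjusted p = 7.42e-17). The netrin receptor UNC5D (-1.49) and CDH20 (-1.42) fell. Of 7623 genes 267 passed, 155 higher and 112 lower, which became 83, 38 higher and 45 lower, without cluster 11; 151 passed without control 1 and 175 without control 2. Cluster 11, whose leading genes include CCL4, EXFABP, FOS and SAA, held 0.214% and 0.557% of control but 25.2% and 24.4% of inhibitor fibroblast-like nuclei. This cluster was drawn from the same counts, so leaving it out lowers its leading genes, EGR1 and THBS1 also among them, by construction. Without it, FOS in fibroblasts was 0.48 (adjusted p = 0.524), UNC5D was -1.19 (adjusted p = 0.0977), and the 346 genes called over these 8 other classes became 162; without control 1 they were 207 and without control 2 they were 212.

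Of 40 matrix genes tested in the fibroblasts 10 fell, among them the collagens COL1A1 (-0.50, from 5519 to 3931 CPM), COL1A2 (-0.36) and COL3A1 (-0.37), the proteoglycan DCN (-0.42) and SPARC (-0.33), and THBS1 rose (1.24). Adjusted over the list alone, 16 fell and 2 rose (median -0.27, camera adjusted p = 7.89e-11; adjusted p = 0.178 with an estimated correlation). Of 16 immediate-early genes 9 rose, 9 adjusted over the list alone (median 1.10, adjusted p = 1.52e-13), and of 69 ribosomal protein genes 17 rose, 42 adjusted over the list alone (median 0.56, adjusted p = 1.08e-23); both had adjusted p = 0.178 with an estimated correlation. Of 11 inflammatory genes CCL4, NFKBIA and NFKBIZ rose, 4 adjusted over the list alone (median 0.63, adjusted p = 0.000287; adjusted p = 0.374 with an estimated correlation). The mitochondrial list (2 of 12 higher, 5 adjusted over the list alone, median 0.29, adjusted p = 0.00085) had adjusted p = 0.667 with an estimated correlation and was lost without control 1 or inhibitor 2. The synaptic list (0 of 25 past edgeR's test, also adjusted over the list alone; median -0.26, adjusted p = 0.0369) had adjusted p = 0.501 with an estimated correlation and was lost without control 2, inhibitor 1 or inhibitor 2 (adjusted p up to 0.149). Without cluster 11, 3 matrix genes of 40 fell and 0 rose, among them COL1A1 (-0.26). There COL1A2 (-0.087), COL3A1 (-0.091), DCN (-0.32), SPARC (-0.35) and THBS1, now at -0.18, did not pass (list median -0.21, adjusted p = 1.04e-07; adjusted p = 0.504 with an estimated correlation). In that fit the immediate-early list had 0 of 11 past edgeR's test (median 0.04, adjusted p = 0.786) and the inflammatory list 0 of 7 (median -0.056, adjusted p = 0.898), with EGR1 at -0.036 and NFKBIZ at -0.36. The ribosomal list had 0 of 69 (median 0.13, camera adjusted p = 0.00363, or 0.691 with an estimated correlation), and the synaptic list did not pass (adjusted p = 0.319). The mitochondrial list still passed there, with 2 of 12 higher (median 0.27, camera adjusted p = 0.000291, or 0.691 with an estimated correlation). Axon guidance passed there (median 0.19, camera adjusted p = 0.0162, or 0.691 with an estimated correlation), but not with cluster 11 (adjusted p = 0.424).

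In meningeal-like nuclei 52 of 3825 genes passed, 33 higher and 19 lower. SAA was 24.8-fold higher on 30 UMIs against 3 (counting interval 7.71 to 127), and FOS rose by 2.21. Both are leading genes of cluster 11, and free RNA from those nuclei stays possible as their source here. TAGLN, a smooth muscle protein, had 3 UMIs against 57 and was 7.66-fold lower (interval 2.49 to 38.3), NBR1 (-2.33) and ZIC5 (-2.26) fell, and TRPM3 fell from 2728 to 1658 CPM (-0.66). The mitochondrial list rose, 7 of 11 (10 adjusted over the list alone; median 0.78, camera adjusted p = 2.69e-15), and the ribosomal list, 7 of 64 (10 adjusted over the list alone; median 0.51, adjusted p = 5.35e-12), both with adjusted p = 0.882 with an estimated correlation. None of the 6 genes chosen by the rule stayed past the test in every fit that left out 1 library. The 52 became 12 without control 1, 5 without control 2, 18 without inhibitor 2 and 1 at equal library totals. Scaling by library size alone gave 11 higher and 10 lower, and DESeq2 called 2.

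In sympathetic neuron-like nuclei 13 of 2956 genes passed, 9 higher and 4 lower. NR4A3 (2.36), FOS (1.47) and mt-COX2 (1.14) rose, and CPNE8 (-1.47), the tumour suppressor APC (-1.41) and RUNX2 (-1.14) fell. The immediate-early list (FOS and NR4A3 of 5, 3 adjusted over the list alone; median 1.22, adjusted p = 0.000568), the mitochondrial list (2 of 11, 5 adjusted over the list alone; median 0.72, adjusted p = 7.17e-09) and, lower, the repair Schwann list (RUNX2 of 6, also 1 adjusted over the list alone; median -0.29, adjusted p = 0.0241) passed; all had adjusted p = 0.857 with an estimated correlation. Of the 6 genes only NR4A3 stayed past the test whichever library was left out, the repair list was lost without control 1 or inhibitor 1, and 4 genes passed without inhibitor 2. Scaling by library size alone, which set the median of all genes at -0.28, gave 8 higher and 72 lower.

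In endothelial-like nuclei edgeR called 0 of 836 genes, with 45 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. FKBP5 (-1.48), TULP1 (-1.08), FOS (2.42), LAMA3 (-1.53) and RPS12 (1.40) had the lowest p, with adjusted p from 0.276 to 0.806; 9 genes passed without control 1, 3 without control 2, 1 without inhibitor 1 and 2 without inhibitor 2. In the cycling nuclei edgeR called 0 of 266, with 19 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom, and DOCK1 (1.78), STMN2 (-1.18), KALRN (-1.93), LAMB1 (1.92) and FKBP5 (-2.14) had the lowest p, with adjusted p of 0.683; 1 passed without control 1, 5 without control 2 and 2 without inhibitor 2. In cluster 5, 11 of 3125 genes passed, among them TTN (3.66), DGKB (2.00) and FOS (1.94), which rose, and FILIP1 (-2.61), ITGA1 (-1.51) and COL8A1 (-1.11), which fell, and of these 6 TTN and FOS stayed past the test whichever library was left out, with 18 genes past it without inhibitor 1. In cluster 8 only TULP1 passed (-0.96), a call lost without control 2 (4 genes passed without control 1, 2 without control 2, 6 without inhibitor 1 and 8 without inhibitor 2), and FOXD1 (-1.40), BNC2 (-0.94), ANTXR2 (2.67) and SLC4A4 (-0.58) followed with adjusted p of 0.105 to 0.108. In cluster 10, where 2 genes passed of 1283, FRMD8 (0.43) rose. It took 51.6% and 50.9% of the UMIs of cluster 10 in control and 58.1% and 57.3% in inhibitor libraries. Genes not past the test followed there with adjusted p from 0.123 to 0.25: PCDH9 (-0.88), SLIT1 (1.51), TTL (2.61), HOXA3 (2.14) and RTN4 (-1.38).

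Mitochondrially encoded transcripts rose as a list in these small classes too, with medians of 0.55 in endothelial nuclei (camera adjusted p = 0.00224), 0.40 in cluster 5 (2.27e-05), 0.52 in cluster 8 (0.0414) and 0.54 in cluster 10 (0.0135). The endothelial libraries did not separate by group. Their nuclei held 11.1 and 3.81 mitochondrial UMIs in the control and 17.6 and 6.91 in the inhibitor libraries, and 11.9 and 5.74 against 21.5 and 10.7 ribosomal ones. The myelin list fell in cluster 10, with 1 of 7 genes past the test and 3 adjusted over the list alone (median -0.59, adjusted p = 0.00117), and the nerve injury list fell in cluster 5 (median -0.27, adjusted p = 0.0177). In endothelial nuclei the ribosomal list rose (median 0.60, adjusted p = 0.00184) and the calcium (median -0.47, adjusted p = 0.00968) and glucocorticoid lists (median -1.09, adjusted p = 0.00727) fell. With an estimated correlation the adjusted p was 0.646 in endothelial nuclei, 0.823 and 0.911 in cluster 5, 0.967 in cluster 8 and 0.692 in cluster 10. Of these 9 calls, the mitochondrial one of cluster 5 and the myelin one of cluster 10 held whichever library was left out. The others were lost in at least 1 such fit, and in 4 of 4 for the mitochondrial list of cluster 8 and the endothelial glucocorticoid list.

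A few genes changed in many classes. FOS was higher in 7 of the 9 classes where it was tested, and lay on the same side in all 9. In satellite glia and meningeal nuclei, free RNA from cluster 11 stays possible as its source, and in other classes as part of it, as set out below. PHLDA2, an imprinted growth regulator in mammals, rose in 5 of 10 classes, EPHA6 and EYS in 4 of 7, METTL22 in 4 of 6, mt-ATP6 in 4 of 10, mt-COX2 and mt-COX3 in 4 of 11, ADAMTS9 in 3 of 10 and BMPR1B in 3 of 6, with a value under 0 in the other 3. TULP1 fell in 7 of 11 classes, from 515 ± 55.0 to 258 ± 10.9 CPM in Schwann cells and from 1216 ± 35.3 to 615 ± 97.7 CPM in fibroblasts, and its values over the 11 classes ran from -1.59 to -0.39. Its neighbour in GRCg7b, FKBP5, a co-chaperone of the glucocorticoid receptor, fell in 4 of 11. Leaving out a library ended the FOS call in meningeal (control 2, inhibitor 1) and sympathetic nuclei (control 2, inhibitor 2) and the TULP1 call in cluster 8. BMPR1B was lost in 3 or 4 of the 4 such fits in each of its 3 classes, and ADAMTS9 in 4 in Schwann cells and 3 in meningeal nuclei. All 4 fits lost EPHA6 in satellite glia and meningeal nuclei, EYS in satellite glia, METTL22 in Schwann cells and satellite glia, FKBP5 in Schwann cells and mt-COX3 in sympathetic nuclei. In 3 of 4 fits the call was lost for PHLDA2 in sensory neurons and mt-COX2, mt-COX3 and FKBP5 in meningeal nuclei.

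**Figure D4:**
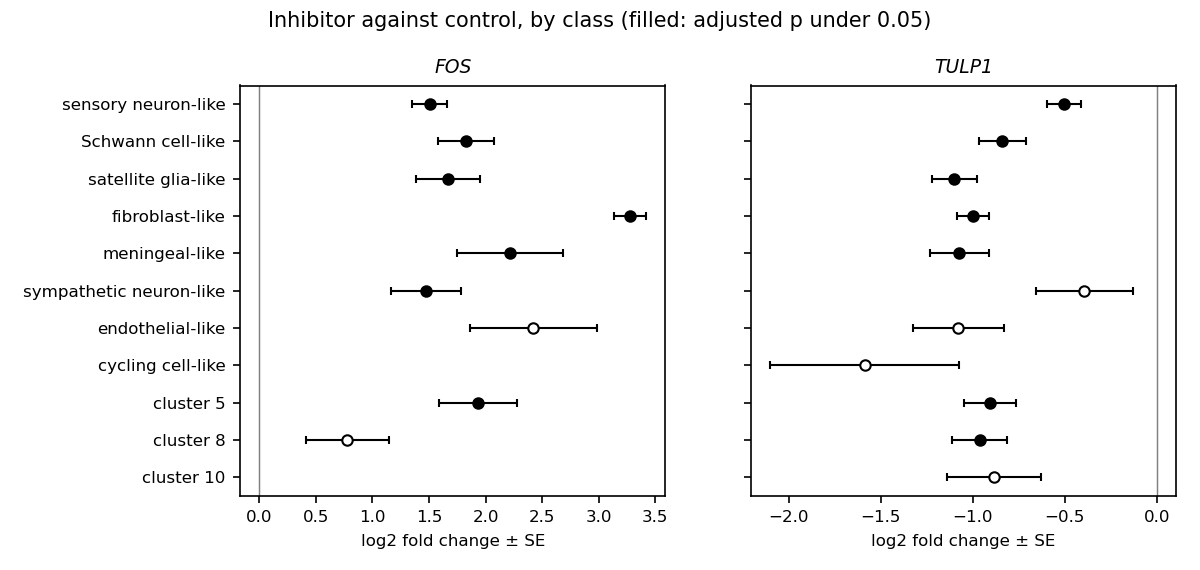
Log2 fold change with SE (x axis), inhibitor over control, of FOS and TULP1 in each class where they were tested (y axis), with filled points for an edgeR adjusted p under 0.05. FOS lies above 0 and TULP1 below 0 in every class shown.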

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

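The median without channel genes, the tests of tissue handling and of fewer nuclei of females, the comparison between classes for cluster 11, and the choice of the classes set beside the neurons for HINTW were made after the results had been seen. The other tests had their bounds written before.

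For 4 of 5751 genes the change from control to inhibitor libraries, called the effect here, differed between sensory neurons and Schwann cells. The test was limma's test of the difference, with 678 genes at an unadjusted p under 0.05. The neurofilament NEFM (0.65) and the surface protein THY1 (0.74) had the higher effect in neurons, and FRMD8 (-0.15) and the phospholipase PLCB1 (-0.77) the lower one, each given as the neuron effect minus the Schwann cell effect. NEFM is among the markers of cluster 7, whose share was larger among inhibitor neurons. THY1 rose by 0.80 in neurons and lay at 0.03 in Schwann cells. The count was 15 without control 1, 0 without inhibitor 1 and 1 without inhibitor 2.

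Between sensory neurons and satellite glia 15 of 6396 genes differed (758 at an unadjusted p under 0.05), 11 of them with effects of opposite sign. The effect was higher in neurons for VSIR (2.70), TSC22D2 (2.26), RPS29 (1.38), the mitochondrial transcript mt-mt-J6367_mgt01 (0.88), YWHAG (0.85) and NEFM (0.58). It was lower in neurons for LOC101750271 (-3.89), IL13RA2 (-2.24), PLA2G4A (-2.20), KATNAL1 (-2.15), LOC112530089 (-2.03), ARID4A (-1.18), TSHZ2 (-0.98), the reelin pathway adaptor DAB1 (-0.96) and DOCK3 (-0.78). RPS29 rose by 1.53 in neurons and lay at 0.05 in satellite glia, and IL13RA2 lay at 0.42 in neurons and rose by 3.22 in satellite glia. LOC101750271 is among the leading genes of the fibroblast-like cluster 11. The count was 35 without inhibitor 1 and 98 without inhibitor 2. No explanation was tested for the differences between classes.

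TRPA1 was lower in sensory neurons of the inhibitor libraries, as were TRPV1, TRPM8 and TRPV3. With equal shares of UMIs per neuron subcluster TRPA1 lay at -0.78 (adjusted p = 0.000172), which argues against a changed mix of these subclusters as the whole cause, although the call on the TRPA1 level was lost without cluster 7 (-0.56, adjusted p = 0.0518). Genes that sensory neurons hold at over 5 times the level of any other class had a median of -0.39 (interval -0.56 to -0.33), or -0.37 (-0.57 to -0.27) without the 3 that are channel genes and -0.30 with equal subcluster shares. Dilution of neuronal RNA by free RNA may thus account for part of the fall, but medians at unequal shares cannot tell it from a changed mix. Among these genes, TMC3, SCN11A, SH2D5 and RIMS4 lead cluster 4, which held 48.8% and 40.3% of control but 37.7% and 34.0% of inhibitor neurons. TRPA1 lay a further -0.27 below the first median, and at -0.78 against -0.30 with equal subcluster shares. An effect of the inhibitor on the expression of its target stays open and was not separately tested.

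Immediate-early and acute inflammatory genes were higher in the inhibitor libraries. If free RNA from the fibroblast-like nuclei of cluster 11 were the source, EXFABP, CCL4 and SAA would accompany FOS in a fixed ratio; in neurons they reached 0.403 of the predicted excess (Poisson interval 0.278 to 0.542), and the bound written before, an upper end under 0.5, was not met. A comparison chosen afterwards argues against 1 such source for all classes. With the error of FOS included, the ratio was 0.403 in neurons (0.276 to 0.588) and 1.39 in satellite glia (0.875 to 2.20). In meningeal nuclei it was 2.11 (Poisson interval 1.40 to 2.98). For satellite glia and meningeal nuclei, such free RNA thus stays possible as the source of the FOS excess. Handling of the tissue before freezing could also raise FOS, which passed in 7 of the 9 classes where it was tested, and it cannot be told apart from the treatment because no label records handling. An effect of the inhibitor stays open as well.

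HINTW and the chromosome W copy of CHD1, which may share reads with their Z copies, were lower in sensory neurons, with a ratio of inhibitor to control of 0.563 (0.508 to 0.623). Fewer nuclei of females would lower them alike in every class, but in fibroblasts and satellite glia together the ratio was 0.822 (0.710 to 0.949). These intervals cover only the counting error of UMIs pooled over the libraries of a group. They are too narrow, because the UMIs gather in some nuclei, so a lack of overlap cannot decide the question. In control 1, 169 deeply sequenced neurons had no UMI of either gene, where Poisson counts would give 69.1. In Schwann cells (0.484, interval 0.346 to 0.670), sympathetic neurons (0.429) and endothelial nuclei (0.555) the ratio lay near that of the neurons, and in meningeal nuclei it was 0.991, so a difference in sex makeup could still account for part of the fall. With equal shares of UMIs per neuron subcluster HINTW lay at -0.81, against -0.91 without, which argues against a changed mix of subclusters as the whole cause. The share of deeply sequenced neurons with a UMI of either gene was 46.9% and 49.1% in control and 39.0% and 35.6% in inhibitor libraries, with 3.58 and 3.54 against 2.37 and 2.46 UMIs per positive neuron.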

How the results depend on the processing

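The fits without cluster 7, without cluster 11, with equal subcluster shares and without the meningeal and spinal cord classes were among those chosen after the data were seen. The fit with thinned nuclei was planned before. Of 367 gene results named, 103 kept their direction and side of the threshold under every alternative that gave a value. The causes of the changes below were not tested. A fit that leaves out 1 library assumes that the lone library varies like those of the other group, and depth limits the smaller classes most.

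The 1652 genes called in differential expression in sensory neurons became 894 with no filter except 1 count, 909 with a stricter filter, 297 with DESeq2, 616 without cluster 7, 716 with equal subcluster shares and 810 to 1140 with 1 library left out. The 43 of Schwann cells became 10 with DESeq2 and 14 to 28 with 1 library left out. The 56 of satellite glia became 93 with no filter, 11 with DESeq2, 28 with limma-voom, 20 at Leiden resolution 0.5, 124 when centred per library and 31 to 40 with 1 library left out. At equal library totals 5 seeds gave 1269 to 1539, 24 to 50 and 34 to 85 in these 3 classes. The 346 of the other classes became 85 with DESeq2, 162 without cluster 11 and 207 to 326 with 1 library left out.

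The TRPA1 level, at -0.66, lay at -0.56 (adjusted p = 0.0518) without cluster 7, at -0.43 (adjusted p = 0.394) with thinned nuclei, and at -0.79 to -0.56 with 1 library left out. FRMD8 in cluster 10 lay at -0.26 with no filter. Without cluster 7, CPLX2 lay at -0.031 and NDUFA5 at -0.30 in neurons. With equal subcluster shares, mt-COX3 lay at -0.031, mt-ND4 at -0.20, mt-ND5 at -0.046 and mt-ND6 at -0.37. Without cluster 11, EGR1 lay at -0.036, MCL1 at -0.16, NFKBIZ at -0.36 and THBS1 at -0.18 in fibroblasts.

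With an estimated correlation camera called 0 lists in each of the 4 sets of tests, where the preset one called 7 in sensory neurons, 5 in Schwann cells, 1 in satellite glia and 20 in the other classes. With fry the counts were 1, 0, 0 and 2. With 1 library left out they were 6 to 7, 0 to 5, 0 to 1 and 13 to 20, and the list immediate-early genes in Schwann cell-like nuclei turned down without control 2, with adjusted p over these fits from 0.000177 to 0.999. The list inflammatory cytokines and NF-kB in fibroblast-like nuclei turned down without cluster 11 (adjusted p = 0.898). The 4 genes whose effect differed between neurons and Schwann cells became 1 with a prior count of 0.5 and 0 to 15 with 1 library left out, and the 15 between neurons and satellite glia became 3 and 12 to 98. Between Schwann cells and satellite glia the limma count of 0 became 0 to 5 (347 at an unadjusted p under 0.05). The 4 class shares past the test became 1 to 5, and the share of non-myelinating Schwann cells lay at -0.10 without the meningeal and spinal cord classes and at -0.41 to 0.32 with 1 library left out.

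Libraries of the 2 groups share only a replicate number. With it as a block, 120 genes passed in satellite glia, 28 between neurons and Schwann cells, 5 between neurons and satellite glia and 2 between Schwann cells and satellite glia, 2 class shares passed, and the share of non-myelinating Schwann cells lay at -0.020. In smaller classes the block gave 41 genes in sympathetic neurons (13 without it), 25 in cluster 5 (11), 19 in cluster 8 (1), 5 in endothelial nuclei (0) and 1 in cycling nuclei (0). Over classes the correlation of libraries with the same number ran from -0.00667 to 0.214, the highest in endothelial nuclei, which does not show that they are pairs.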

Other observations

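The values here were chosen after the results had been seen. Sensory neurons held 18.8 and 15.4 ribosomal protein UMIs per nucleus in the control and 19.7 and 23.4 in the inhibitor libraries, and satellite glia 4.23 and 4.62 against 3.97 and 4.10. Mitochondrially encoded transcripts stood at 17.4 and 16.8 UMIs per sensory neuron in the control libraries, at 17.6 in inhibitor 1 and at 27.6 in inhibitor 2. As shares of UMIs without FRMD8 they took 0.774% and 0.851% in the control and 1.21% and 1.41% in the inhibitor libraries. Both inhibitor libraries thus lay above the controls by share, and only inhibitor 2 clearly so per nucleus.

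Of 41 tested genes that cluster 10 held at over 5 times the level of the other classes, the median in sensory neurons was -0.15 (interval -0.27 to 0.12), with 1 higher and 2 lower.

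TRPA1 and TRPM8 were also tested within single neuron subclusters, and the difference between subclusters was not tested. In subcluster 0, led by TRPM8 and TRPA1, TRPA1 lay at -1.03 (adjusted p = 0.003), a call lost without control 1 (-1.15, adjusted p = 0.214) and without control 2 (-0.86, adjusted p = 0.272). TRPM8 lay at -1.03 there (adjusted p = 0.00403), a call lost without control 1 (-0.74, adjusted p = 0.685). In subcluster 5 TRPA1 lay at -1.65 (adjusted p = 0.0186), with 167 and 58.1 CPM in the control and 44.5 and 27.3 CPM in the inhibitor libraries. That call was lost without control 1 (-0.76, adjusted p = 0.619) and without inhibitor 2 (-1.35, adjusted p = 0.0742). TRPM8 lay at -2.34 in subcluster 5 (adjusted p = 0.0186), a call lost without control 1 (-1.31, adjusted p = 0.761) and without inhibitor 2 (-1.94, adjusted p = 0.0684). In subclusters 3 and 4 TRPA1 did not pass (-0.13 and -0.17), nor did TRPM8 in subcluster 4 (0.28, adjusted p = 0.797) and in subcluster 1 (adjusted p = 0.44).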
